A study of Mus musculus with 4 samples.

How the data were processed

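Gene expression was measured on single-channel Affymetrix mouse arrays hybridised with biotin-labelled total RNA. The cells came from lines established from ErbB2-driven mammary tumours of female FVB mice of the MMTV-NIC model, in which an activated ErbB2 receptor and Cre recombinase are expressed from the same transcript in the mammary epithelium. Per the labels, cells received either the vehicle DMSO or 2 µM GSK126 for 96 h before harvest. GSK126 blocks the methyltransferase EZH2, which places the repressive histone mark H3K27me3. Each group holds 2 arrays, and groups and replicate numbers were taken from the sample titles.

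The deposited values are log2 expression values, summarised by robust multi-array averaging over core exons in Expression Console, per the labels. The submitters' processing notes name Affymetrix Power Tools, with no version. The genome build is not given in the sources used here, so no coordinates are printed. Scanner files and scan dates were not used here, and a difference between hybridisation days was not assessed. The values ran from 0.63 to 13.6, with array medians over all probe sets of 4.74 and 4.73 for the DMSO arrays and 4.79 and 4.78 for the GSK126 arrays. The labels give the log2 scale and the method but not the centring, which was left as deposited. For arrays, the number of arrays limits the precision, and no counting error applies.

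Of the 41345 probe sets, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 16010 none. No gene was named from a probe set with several symbols. Symbols were compared with a RefSeq mouse gene table (assembly GRCm38.p6) through Entrez identifiers. This matched 23328 probe sets and updated 0 symbols. The 22180 named genes were each represented by the probe set with the highest mean over the 4 arrays, a choice that mattered for 1082 genes with several probe sets. Arrays cannot separate transcripts that share probe sequence. Genes with near-identical relatives, such as Ly6c2, Ceacam10, Ctla2a, Ctla2b, H1f5 and members of the Ifit, Oas and Gbp families, are therefore uncertain as single genes.

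Differences were fitted as GSK126 minus DMSO with limma 3.58.1 in R 4.3.3, using an intensity trend in the prior variance, a two-sided moderated test and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 5.57. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 28 lists, each of which had at least 5 genes measured. Of their 736 memberships, 664 were measured. For each list, genes were also adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest increases and 12 largest decreases past the threshold whose groups do not overlap, passing over predicted and uncharacterised genes, small RNAs, olfactory and vomeronasal receptors and pseudogenes. It also named Ezh2, Ezh1, Eed, Suz12 and Erbb2 in every case, and up to 4 members of each list with the smallest p.

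The labels do not say whether replicates are separate cultures or separate lines. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. Camera with the preset correlation compares the genes of a list with all other genes. Its p-values rest largely on the spread between genes, and small ones do not measure how far arrays would repeat. Pairs of arrays shared between 142 and 181 identical values out of all probe sets, so no array was a copy of another. Alternatives were a prior variance without the trend, a robust prior, leaving out genes below the 40th percentile of mean level, averaging a gene's probe sets, testing all probe sets, centring each array on its median, quantile normalization, the replicate number as a block, leaving out each array in turn, camera with an estimated correlation and the directional fry test.

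The procedure was tested on simulated data with the real means and prior variances of the 22180 genes and 200 changed genes, in 20 simulations. It found 63.2% of genes changed by 1 on the log2 scale and 98.6% of those changed by 2, with 5.0% false calls. Gene variances were drawn from the prior that the same fit had estimated, with its intensity trend. These shares therefore do not check whether that model holds for the real arrays. A shift of the DNA replication list by 0.3 was called in 20 of the 20 simulations with the preset correlation and in 0 of 20 with an estimated one. Unchanged data gave 2 list calls over all 20 simulations. The simulated genes varied independently of each other, so these list results do not cover lists whose members vary together.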

Results

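Expression was profiled in cells from ErbB2-driven mouse mammary tumours after 96 h with 2 µM GSK126 (n = 2 arrays) or with the vehicle DMSO (n = 2 arrays), to record the transcriptional response to an inhibitor of H3K27 trimethylation. Correlations between arrays over all probe sets lay between 0.981 and 0.988. GSK126 replicate 2 correlated least with the others, at 0.981 to 0.983, and the 2 DMSO arrays correlated at 0.988. GSK126 replicate 1 correlated more with the DMSO arrays (0.987 and 0.986) than with GSK126 replicate 2 (0.981), so the treated arrays did not group together. Values below are log2 expression values as mean ± SD with n = 2 arrays, and changes are GSK126 minus DMSO on the log2 scale with their standard error (SE). For lists that were not called, the lowest and highest median over the 4 fits that leave out 1 array are given as the leave-out range. Genes are called dim in a group whose mean is below 4.77, the 40th percentile of mean level, and for these the size of a change is uncertain.

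The largest increase was that of Mcpt8, a serine protease of the mast cell protease family, which rose from 6.93 ± 0.25 to 9.77 ± 0.19, a 7.17-fold change (adjusted p = 0.000911). Iigp1, an interferon-inducible GTPase, rose 4.03-fold (5.28 ± 0.09 to 7.29 ± 0.16, adjusted p = 0.00259), and the antiviral genes Ifit1 and Rsad2 rose 2.79-fold and 2.53-fold. The collagenase gene Mmp13, dim in DMSO, rose from 4.06 ± 0.19 to 5.71 ± 0.05, and the fibronectin gene Fn1 rose 2.41-fold. Ptgs2, which encodes the inducible cyclooxygenase, rose 2.59-fold. The largest decrease was that of Atp6v1b1, a subunit of the vacuolar proton pump, which was 3.55-fold lower with GSK126 (9.73 ± 0.06 to 7.90 ± 0.04, adjusted p = 0.000911). Hey1, a transcriptional repressor induced by Notch signalling, was 3.01-fold lower (8.18 ± 0.08 to 6.59 ± 0.19, adjusted p = 0.00582). Gabrp, a subunit of the GABA-A receptor, fell from 6.13 ± 0.06 to a dim 4.55 ± 0.21, and the casein gene Csn1s1 fell by 0.92 on the log2 scale.

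In all, 96 of 22180 genes passed the threshold, 58 of them higher and 38 lower with GSK126. Of these, 35 changed at least 2-fold, 26 upward and 9 downward. With each array centred on its median the split was 63 higher and 65 lower. All 96 had GSK126 values on 1 side of both DMSO values, which held for 40.1% of all genes against 33.3% by chance. At unadjusted p under 0.05 there were 2346 genes, 1030 higher and 1316 lower, against 1109 by chance. The count of calls rested on having all 4 arrays. It was 4 without DMSO replicate 1, 2 without DMSO replicate 2 and 0 in limma without GSK126 replicate 1 or replicate 2, where 2100 and 1771 genes had an unadjusted p under 0.05. It was also 0 in limma without the intensity trend, with 1964 genes at an unadjusted p under 0.05, and 149 when dim genes were left out. With the replicate number as a block the count was 10. With all probe sets tested one by one it was 0 in limma, where 2921 had an unadjusted p under 0.05.

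**Figure D1:**
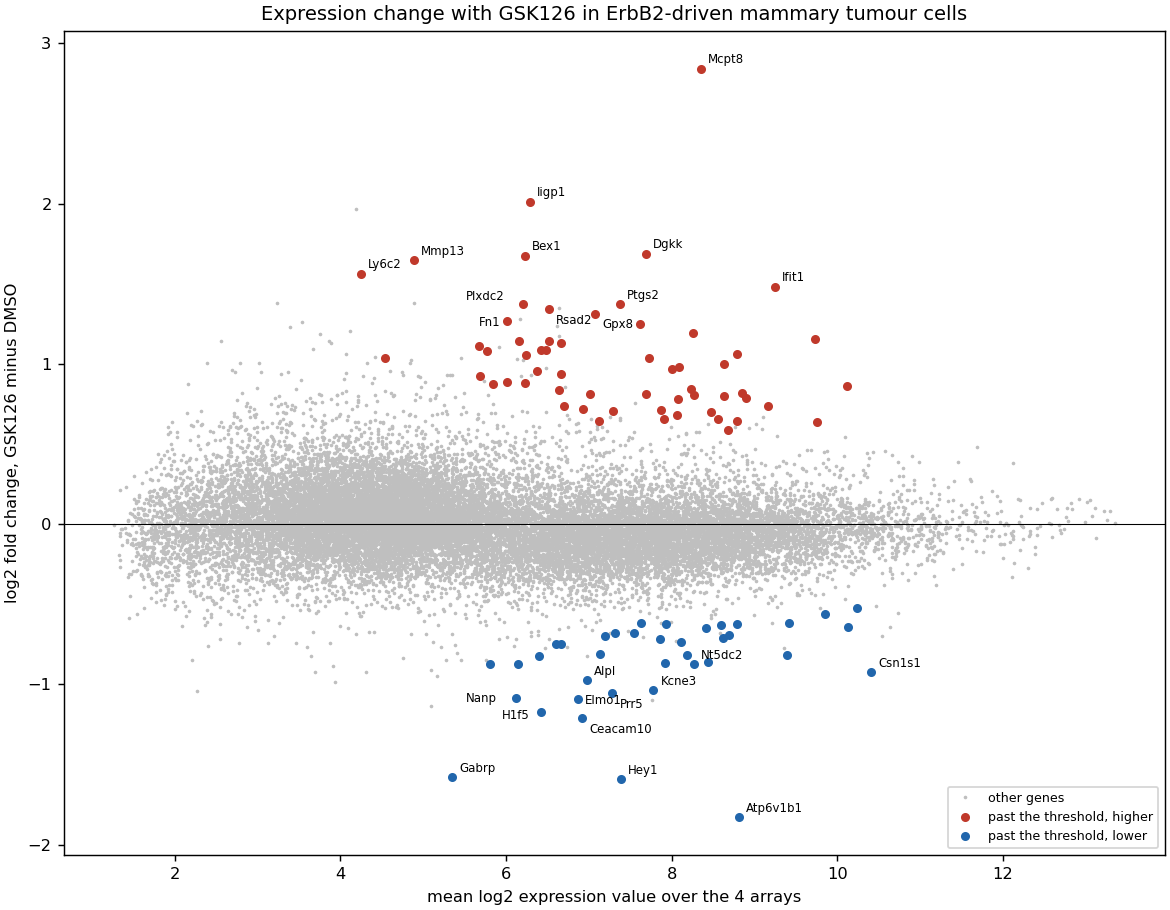
Each point is 1 of the 22180 genes, with its mean log2 expression value over the 4 arrays on the horizontal axis and its log2 fold change (GSK126 minus DMSO) on the vertical axis. The 58 genes past the threshold and higher are red, the 38 lower are blue, and the 24 genes named by rule are labelled, from Mcpt8 at 2.84 to Atp6v1b1 at -1.83.

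The remaining genes among the 12 largest increases were Dgkk (1.69), Bex1 (1.68), Ly6c2 (1.56), Plxdc2 (1.38) and Gpx8 (1.31), with SEs from 0.13 for Bex1 to 0.20 for Ly6c2. Ly6c2 was dim in DMSO, at 3.46 ± 0.15, and reached 5.02 ± 0.34. The remaining decreases were Ceacam10 (-1.21), the linker histone gene H1f5 (-1.17), Elmo1 (-1.09), Nanp (-1.09), Prr5 (-1.06), the potassium channel subunit gene Kcne3 (-1.04), the alkaline phosphatase gene Alpl (-0.98) and Nt5dc2 (-0.87). Averaging the probe sets of a gene ended the calls of Alpl (-0.68, adjusted p = 0.0942) and Nanp (-0.78, adjusted p = 0.0564).

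**Figure D2:**
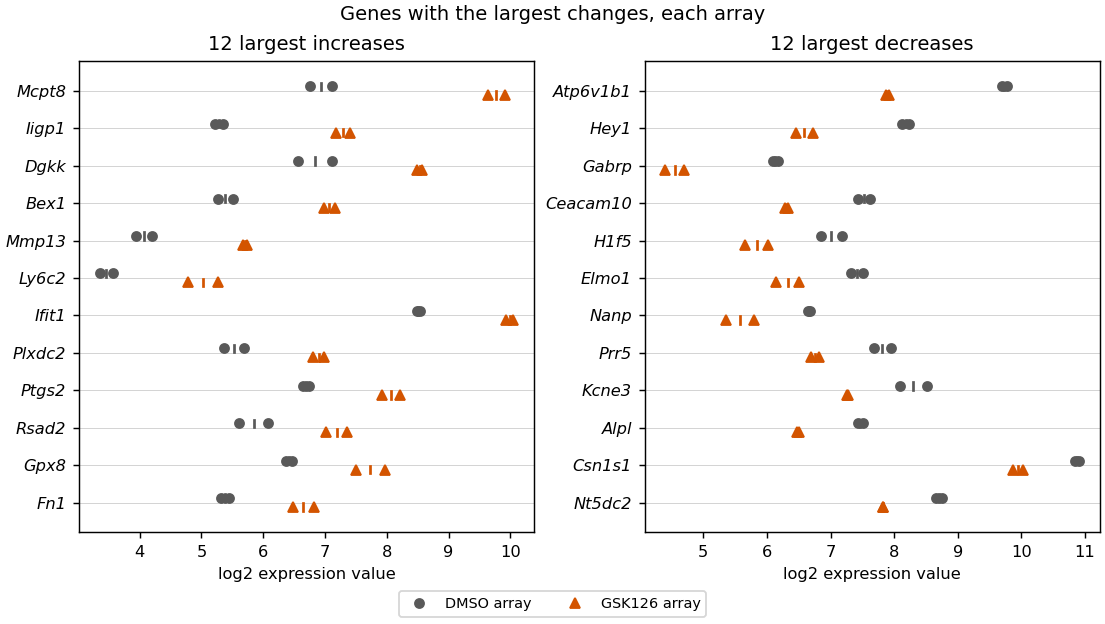
Log2 expression values on each array (horizontal axis) of the 12 genes with the largest increases and the 12 with the largest decreases past the threshold. Grey circles are the 2 DMSO arrays, orange triangles the 2 GSK126 arrays and vertical ticks the group means, and in each gene the groups do not overlap.

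Interferon-stimulated genes rose as a group. Their median change was 0.35 over 42 genes measured (interquartile range 0.15 to 0.59), and camera gave an adjusted p of 7.61e-22. The call ended with an estimated correlation (adjusted p = 0.134). Over all genes tested, 8 members passed the threshold, all higher, and 34 did not. Adjusted over the list alone, 22 rose and 0 fell, with 24 higher and 0 lower at an unadjusted p under 0.05. Besides Ifit1 and Rsad2, the members past the threshold over all genes included Cmpk2 (1.97-fold), a mitochondrial nucleotide kinase, Usp18 (1.82-fold), which removes the ubiquitin-like protein ISG15, and Zbp1 (1.72-fold), a sensor of Z-form nucleic acids. Cd68, a marker of macrophages, rose alongside (2.00-fold, 8.14 ± 0.09 to 9.14 ± 0.03, adjusted p = 0.010), while the list of 19 immune cell markers had a median change of -0.05 (leave-out range -0.10 to 0.03) and an adjusted p of 0.980.

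Genes of nucleic acid sensing also rose as a list (median 0.12, 17 measured, adjusted p = 0.00186), and the call ended with an estimated correlation (adjusted p = 0.426). The median without DMSO replicate 2 was 0.06, and 0.08 without GSK126 replicate 2. Only Ifi204 (1.94-fold) and Zbp1, which the interferon list also holds, passed the threshold, both over all genes and adjusted over the list alone. Aim2 (0.55, dim in both groups) and Ikbke (0.27) did not pass it. Cytokines and chemokines had a median of 0.17 over 28 genes and an adjusted p of 0.000422, which became 0.549 with an estimated correlation and 0.263 in the directional fry test. The median was 0.08 without DMSO replicate 2. None of these genes passed over all genes tested in limma, where 10 were higher and 1 lower at an unadjusted p under 0.05. Cxcl10 was close to the threshold there (adjusted p = 0.0562) and passed with a robust prior (0.0449), without dim genes (0.0243) and after quantile normalization (0.0456). Adjusted over the list alone, 6 rose, among them Cxcl10 (1.02), Ccl5 (0.58) and Csf1 (0.45), and Tnf fell by 0.43. Of the MHC class I antigen presentation genes (median 0.04, leave-out range 0.02 to 0.09, 19 measured, adjusted p = 0.127), the immunoproteasome gene Psmb8 (0.49) passed when adjusted over the list alone and the peptide transporter gene Tap1 (0.25) did not. MHC class II genes had a median of -0.02 over 9 genes (leave-out range -0.15 to 0.11), while their mean was 0.02 and the test pointed upward, with an adjusted p of 0.901.

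DNA replication genes fell. In the values as deposited, all 35 members measured had a lower mean with GSK126, with a median of -0.29 (interquartile range -0.35 to -0.18), and camera gave an adjusted p of 2.83e-17. With an estimated correlation the call ended (adjusted p = 0.134). Cdc6, which loads the replicative helicase, passed over all genes (8.24 ± 0.07 to 7.62 ± 0.003, adjusted p = 0.0455), and 34 did not. Adjusted over the list alone, 16 fell and 0 rose, among them the helicase subunit gene Mcm7 (-0.44), the chromatin assembly gene Chaf1b (-0.40) and Uhrf1 (-0.38), which maintains DNA methylation. At an unadjusted p under 0.05, 21 were lower and 0 higher. Mitosis genes had a median of -0.06 over 38 genes (leave-out range -0.09 to -0.03) and an adjusted p of 0.104, with 0 past the threshold in limma over all genes or over the list alone and 2 lower at an unadjusted p under 0.05. The lowest p among them were those of Aurkb (-0.25) and Ncapd2 (-0.30). This list passed as lower without DMSO replicate 1 (0.0473) and without GSK126 replicate 2 (0.0359). CDK inhibitors and p53 targets had a median of 0.08 over 23 genes (leave-out range 0.07 to 0.12) and an adjusted p of 0.0654, and passed as higher when dim genes were left out (0.0143), after quantile normalization (0.0154) and without DMSO replicate 1 (0.0390). Within that list Cdkn2d, an inhibitor of cyclin D kinases, fell by 0.45 when adjusted over the list alone, while Mdm2 (0.32) and Ccng1 (0.27), both induced by p53, did not pass.

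Cholesterol biosynthesis genes rose slightly, with a median of 0.19 over 19 genes (interquartile range 0.02 to 0.29) and an adjusted p of 9.13e-05. The call ended with an estimated correlation (adjusted p = 0.380). No member passed over all genes tested in limma, where 7 were higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 5 rose and 0 fell, including the sterol enzyme genes Lss (1.29-fold), Nsdhl (1.31-fold) and Msmo1 (1.24-fold), and Insig1 (1.24-fold), which holds back sterol synthesis.

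Genes linked to epithelial-mesenchymal transition (EMT) were called upward with a median of 0.12 over 22 genes (adjusted p = 0.0412), but members moved both ways. The call ended with an estimated correlation (adjusted p = 0.611), in the directional fry test (0.343), without dim genes (0.0665), with averaged probe sets (0.0666), without DMSO replicate 2 (0.214) and without GSK126 replicate 1 (0.253). The median was 0.06 without GSK126 replicate 1. Fn1, the receptor kinase gene Axl (1.64-fold) and the collagen crosslinking enzyme gene Lox (4.02 ± 0.11, dim, to 5.06 ± 0.01) rose, and Tgfb3, a TGF-beta ligand, fell by 0.56 on the log2 scale. Adjusted over the list alone, 5 rose and 2 fell. Among basal and myoepithelial markers (median 0.003, leave-out range 0.002 to 0.04, mean -0.0003, 20 measured, adjusted p = 0.916), the oxytocin receptor gene Oxtr fell by 0.75. When adjusted over the list alone, 3 fell, among them Oxtr and Id4 (-0.43), and 2 rose, Tagln (0.51, dim in DMSO) and Snai2 (0.56). Luminal epithelial markers had a median of -0.04 over 24 genes (leave-out range -0.08 to 0.01) and an adjusted p of 0.329, and Cldn4, a tight junction gene, rose by 0.39 when adjusted over the list alone. At an unadjusted p under 0.05, 5 luminal markers were lower and 1 higher, and Elf5 (-0.38), Elf3 (-0.32) and Xbp1 (-0.22) were among the lower. Milk and alveolar genes (median -0.05, leave-out range -0.08 to -0.01, 17 measured, adjusted p = 0.104) held 1 decrease, Csn1s1, and 1 increase, that of Xdh (1.72-fold), the xanthine oxidoreductase of the milk fat globule. At an unadjusted p under 0.05, 6 of these genes were lower, among them Wfdc3 (-0.36) and Csn3 (-0.28), and 1 was higher.

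Messenger RNA of the drug target did not pass the threshold. Ezh2 was at 9.52 ± 0.08 in DMSO and 9.33 ± 0.06 with GSK126 (change -0.19, SE 0.09, adjusted p = 0.499). Its paralog Ezh1 (0.11) and the partners Eed (-0.14) and Suz12 (-0.08) did not pass either, and Suz12 turned to 0.03 without DMSO replicate 2. Since the drug acts on the enzyme, these values do not check the labels. The list of PRC2 subunits and H3K27 demethylases had a median of -0.08 over 13 genes (leave-out range -0.19 to -0.05) and an adjusted p of 0.199. Erbb2, the gene of the driver receptor, was at 9.0 ± 0.04 and 8.85 ± 0.001 (change -0.15, SE 0.08, adjusted p = 0.563). Whether its probe set reads the endogenous gene, the transgene or both was not checked. The ErbB receptors and ligands had a median of 0.06 over 15 genes (leave-out range -0.04 to 0.08, adjusted p = 0.552). MAPK output genes had a median of -0.09 over 17 genes and an adjusted p of 0.102, and passed without DMSO replicate 2 (median -0.18, adjusted p = 0.0127), whereas the median was -0.002 without DMSO replicate 1. Etv5, a transcription factor induced by MAPK signalling, was 1.82-fold lower (adjusted p = 0.0311), although the average of its probe sets did not pass (-0.49, adjusted p = 0.145).

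Classes of genes that are often marked by H3K27me3 were not called. Hox genes had a median of -0.06 over 36 genes (adjusted p = 0.496), which ran from -0.15 without GSK126 replicate 1 to 0.002 without GSK126 replicate 2, with 0 at an unadjusted p under 0.05 in limma. Developmental transcription factors had a median of -0.01 over 78 genes (adjusted p = 0.601), with 0 higher and 4 lower at an unadjusted p under 0.05, the lowest p being that of Dlx3 (-0.82, SE 0.19, adjusted p = 0.182). Without GSK126 replicate 1 this list passed as lower, with a median of -0.11 and an adjusted p of 0.00681, whereas its median turned to 0.07 without GSK126 replicate 2 and to 0.003 without DMSO replicate 1. Germline genes had a median of -0.01 over 22 genes (leave-out range -0.05 to 0.02), while their mean was 0.01 and the test pointed upward (adjusted p = 0.881), and Mael, dim in both groups, was at 0.54 (SE 0.24). Imprinted genes had a median of 0.02 over 21 genes (leave-out range -0.09 to 0.11, adjusted p = 0.557), and Phlda2, an imprinted growth regulator, fell by 0.72 when adjusted over the list alone. It did not pass over all genes (adjusted p = 0.0908), except without dim genes (0.0452) and with centred arrays (0.0463).

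Other cell types and stress programmes gave no list call. Adjusted p was 0.329 for fibroblast markers (median 0.07), 0.630 for endothelial markers (0.01) and 0.283 for adipocyte markers (0.04). The sign of these medians depended on single arrays, with leave-out ranges of -0.05 to 0.13 for fibroblast, -0.18 to 0.19 for endothelial and -0.03 to 0.15 for adipocyte markers. Apoptosis regulators of the Bcl2 family had a median of -0.13 and an adjusted p of 0.104, which passed at 0.0311 without GSK126 replicate 1 (median -0.19), whereas the median turned to 0.01 without GSK126 replicate 2. The unfolded protein and integrated stress response had a median of -0.03 (leave-out range -0.05 to -0.02), a mean of 0.004 and an adjusted p of 0.916, and ribosomal proteins a median of -0.06 (leave-out range -0.10 to -0.04) and an adjusted p of 0.104. Hypoxia and glycolysis genes had a median of -0.03 (leave-out range -0.002 to 0.04), while their mean was 0.04 and the test pointed upward (adjusted p = 0.462).

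**Figure D3:**
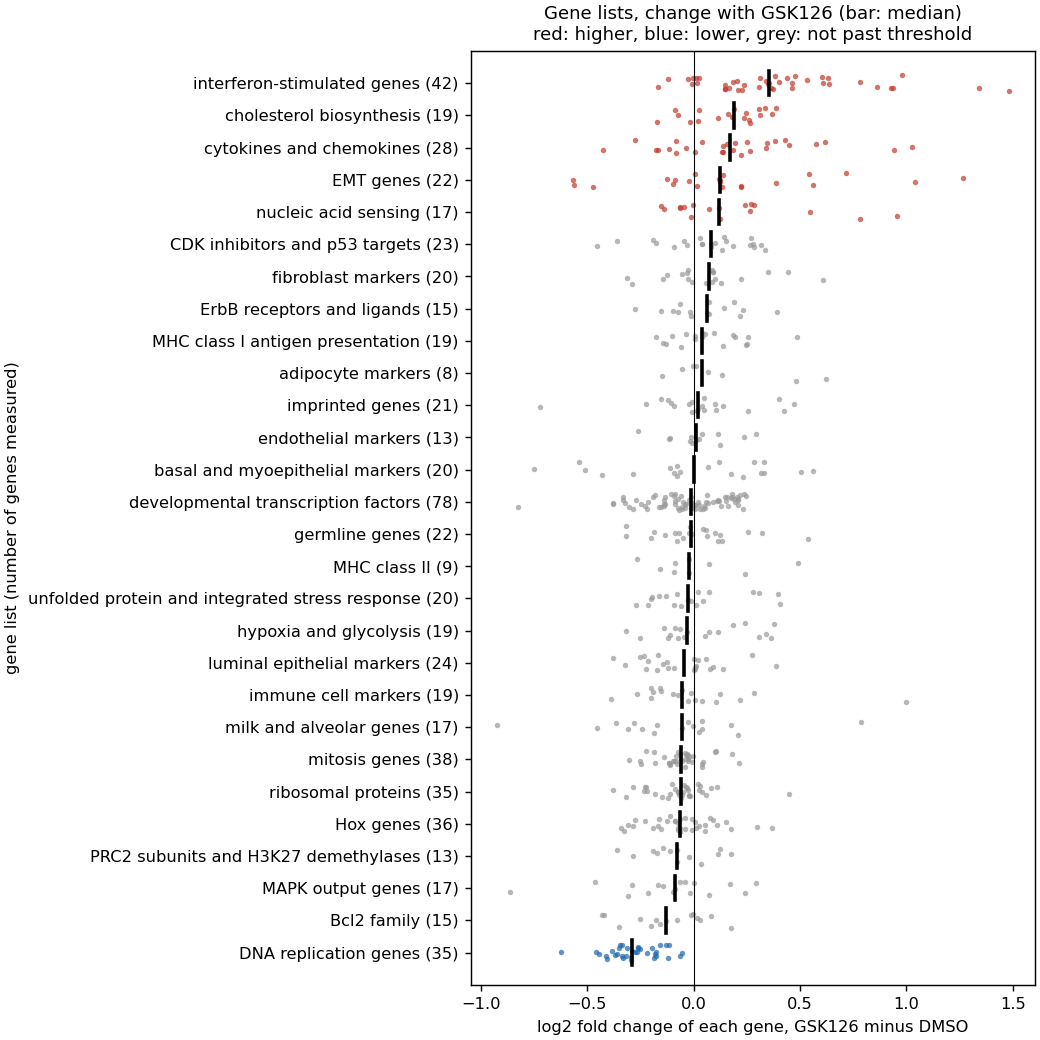
Log2 fold changes (GSK126 minus DMSO, horizontal axis) of the members of the 28 gene lists (vertical axis), 1 point per gene, with a black bar at each median. The 5 lists called upward by camera are red and the list called downward is blue, with medians from 0.35 for interferon-stimulated genes to -0.29 for DNA replication genes, and grey lists did not pass the threshold.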

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

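All alternatives below were fixed before the data were examined. All 96 called genes kept their direction with centred arrays, after quantile normalization and with averaged probe sets. The other alternatives that tested them could not turn the sign of genes whose groups do not overlap. Of the 96 genes, 96 stayed past the threshold with a robust prior, 95 after quantile normalization, 92 with centred arrays, 90 with averaged probe sets and 94 of the 94 tested without dim genes. Averaging could change the values of only the 5 called genes with several probe sets, and each of these lost its call. They were Alpl, Nanp, Etv5, Slc29a3 (-0.17, adjusted p = 0.602) and Acss1 (-0.33, adjusted p = 0.396). The 6 list calls held without the trend, after quantile normalization, with centred arrays and with the replicate block. Of the other alternatives, leaving out dim genes and averaging probe sets ended that of EMT genes (0.0665 and 0.0666).

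Leaving out dim genes raised the count of calls to 149, with 66 decreases, and centring raised the decreases to 65. Named genes that passed only under alternatives were Cxcl10 (robust prior, without dim genes, quantile normalization) and Phlda2 and Dll1 (both without dim genes and with centred arrays). Without the intensity trend, 0 genes passed in limma, 0 of them higher, 0 lower and 0 at least 2-fold (1964 at an unadjusted p under 0.05). With all probe sets tested one by one, 0 passed likewise (2921 at an unadjusted p under 0.05). The prior degrees of freedom were then 2.97 against 5.57. Leaving out 1 array gave 0 to 4 calls, with 0 to 3 increases, 0 to 1 decreases and 0 to 4 at least 2-fold. These fits have fewer samples, and the lone array was assumed to vary like the other group. The unadjusted count ranged from 1771 to 2100. EMT genes ranged from 0.0122 to 0.253.

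With an estimated correlation 0 lists passed, and the adjusted p was 0.134 for interferon-stimulated genes, 0.134 for DNA replication, 0.380 for cholesterol biosynthesis, 0.426 for nucleic acid sensing, 0.549 for cytokines and chemokines and 0.611 for EMT genes. Over all alternatives other than leaving out an array, the adjusted p ran from 4.38e-26 for interferon-stimulated genes, 3.82e-16 for DNA replication, 6.58e-07 for cholesterol biosynthesis, 4.03e-05 for nucleic acid sensing, 0.000275 for cytokines and chemokines and 0.0181 for EMT genes up to these values. For DNA replication, the estimated correlation also missed a simulated shift of 0.3 in 20 of 20 simulations, and shifts of the other lists were not simulated. Simulated genes varied independently, so this does not tell which correlation is right for the real lists. The estimated correlations were -0.01 for interferon-stimulated genes, -0.006 for DNA replication, -0.05 for cholesterol biosynthesis and -0.06 for nucleic acid sensing. As these lie below the preset 0.01, a stronger correlation between members did not end these calls. For cytokines and chemokines (0.07) and EMT genes (0.15) the estimate was above the preset value. In the directional fry test 4 lists passed, and cytokines (0.263) and EMT genes (0.343) did not. Deviations of arrays with the same number correlated at -0.03, so no shared deviation was seen. With 2 arrays per group this cannot tell whether arrays of the same number share a culture, line or batch. With the replicate number as a block, 10 genes passed, 8 higher and 2 lower, and 10 at least 2-fold. For the changes without a stated reason the cause was not tested.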

Other observations

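The tests of immune cell RNA, of a smaller share of cycling cells and of classical Polycomb targets were chosen after the result was seen, as were the 4 further gene lists. These lists were tested without the genes that first drew attention to them. Other members stayed in, also where their change was already known. The genes named in the next paragraphs were chosen after their values were seen.

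Beyond the fixed lists, interferon-inducible GTPases other than Iigp1 rose as a list (median 0.39 over 14 genes, of which 5 are also in a fixed list, camera adjusted p = 4.93e-08). With an estimated correlation the call ended (adjusted p = 0.105). The 9 members outside the fixed lists gave a median of 0.30 and a camera adjusted p of 0.000931. They include Gbp7, which had already passed over all genes in limma (adjusted p = 0.0455), so both tests partly repeat known increases. Adjusted over the list alone, 8 rose and 0 fell, among them Gbp7 (0.65), Gbp10 (0.57) and Irgm2 (0.34). The list of serine and one-carbon synthesis genes other than Psat1, which also holds amino acid transporter genes, fell (median -0.13 over 13 genes, camera adjusted p = 0.0177). With an estimated correlation the call ended (adjusted p = 0.396). The 11 outside the fixed lists gave an adjusted p of 0.0392. Psat1 itself, which acts in serine synthesis, fell by 0.74 (adjusted over all genes). Adjusted over the list alone, Shmt2 (-0.39), Aldh18a1 (-0.49) and Slc1a5 (-0.60) fell. Of these, Aldh18a1 is a gene of proline synthesis and Slc1a5 a glutamine transporter gene. Phgdh, the first enzyme of serine synthesis, was at 0.20 and did not pass, nor did Psph (-0.17) or Mthfd1 (-0.01). Of the 13 members 11 were lower and 2 higher, and a fall of the synthesis pathway itself was not shown.

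Notch pathway genes other than Hey1 did not pass (median -0.07 over 22 genes, adjusted p = 0.0634), although Hes1 (-0.51) and the ligand gene Dll1 (-0.61) fell when adjusted over the list alone. Over all genes Dll1 did not pass (adjusted p = 0.0646), except without dim genes (0.0342) and with centred arrays (0.0488). Acute phase and NF-kB genes other than Saa3, Ptgs2 and S100a8 did not pass either (median 0.11 over 17 genes, adjusted p = 0.0652). Within them Orm2 (1.03), Serpina3n (1.10) and S100a9 (0.63, dim in DMSO) rose when adjusted over the list alone, and the regulator Nfkbia was at -0.13. Saa3 rose 2.38-fold and S100a8 1.67-fold over all genes.

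For the rise of interferon-stimulated genes, 0 of 10000 random lists matched on mean level had a median as high, and leaving out 1 array gave medians of 0.30 to 0.38, which argues against a shift of all genes of like brightness and against a single deviant array. RNA of immune cells in the treated cultures was not settled. Over all 19 immune markers the median change was -0.05 (95% bootstrap interval over genes -0.16 to 0.04), below the 0.35 of the interferon list. Their median level with GSK126 was 4.34, against 8.32 for interferon-stimulated genes. However, 13 of the 19 were below the 40th percentile of mean level, where the size of a change is uncertain. The other 6 had a median change of 0.073 with a 95% bootstrap interval over genes of -0.06 to 0.56, which includes 0.35. Of these 6, Cd68 rose by 1.00, while Cd14 (0.11), Csf1r (0.12), Nkg7 (0.04), Coro1a (-0.03) and Fcer1g (-0.10) did not pass the threshold. Genes known from leukocytes were also among the largest increases, namely Mcpt8 of basophils (2.84, to 9.77) and Ly6c2 of monocytes (1.56, to 5.02), and what raised these was not tested. A response to the inhibitor may underlie the rise, and a difference between the cultures in density or handling stays open too, as the labels give no batch.

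For the fall of DNA replication genes, 0 of 10000 matched lists had a median as low, and leaving out 1 array gave medians of -0.32 to -0.25. Mitosis genes lay 0.23 above them (95% bootstrap interval over genes 0.17 to 0.29), which argues against a smaller share of cycling cells as the whole cause. The interval treats genes as independent and does not cover the spread between arrays. A smaller share of cells in S phase, or lower transcription of these genes within cells, could give the pattern, and neither was tested.

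The rise of cholesterol biosynthesis genes was likewise not matched by any of the random lists (0 of 10000 as high), and leaving out 1 array gave medians of 0.14 to 0.23. Lower sterol supply in the treated cultures could give the pattern and was not tested.

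The 3 possible splits of the 4 arrays into 2 and 2 are too few for a share under 0.05. The real split gave 96 genes, 1 split in 3 reached that count, and the highest of the others gave 0 in limma (670 and 736 genes at an unadjusted p under 0.05).

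Whether the inhibitor switches on classical Polycomb targets could not be told from these arrays. The 136 Hox, developmental transcription factor and germline genes together had a median of -0.029, and 0 of them passed the threshold in limma. This lies below the range of -0.01 to 0.07 that holds 95% of 10000 lists matched on mean level, and 26 of 10000 were as low as the Hox genes alone, which points away from derepression but treats genes as independent. The sign of the pooled median depended on single arrays, as it was -0.09 without GSK126 replicate 1 and 0.03 without GSK126 replicate 2. Of these genes, 83 were below the 40th percentile of mean level (4.77). Among called genes that changed at least 2-fold, 3 rose from below the 40th percentile of mean level (Lox, Ly6c2 and Mmp13) and 1 fell to below it (Gabrp). These 4 genes are too few to tell (two-sided exact binomial p = 0.625 over genes, where 0.125 is the smallest that 4 genes can give).

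Called increases may cluster along the genome. Of the 58 increased genes, 9 had another within 2 places in the order of tested genes, against a mean of 0.63 in 10000 random draws. Unlike the random lists above, these draws were not matched on mean level. Any clustering of genes of like level along the genome is therefore not allowed for. With pairs of like-named genes left out, 6 remained, against 0 to 4 in the central 95% of draws. These were Rsad2 with Cmpk2, Gsn with Stom, and Ctla2b with 4930486L24Rik. Without the last pair, 4 remain, which is within the range of the draws. Rsad2 and Cmpk2 are both interferon-stimulated, so a shared response could account for that pair. The 38 decreased genes held 2 such neighbours, Kcne3 and Lipt2, within the range of the draws.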
